A study of Mus musculus with 48 samples.

How the data were processed

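Bulk RNA sequencing was done on hippocampal microglia of C57BL/6 mice that received a single 8 Gy whole brain dose, or a sham procedure, on postnatal day 21. Cells were released by mild enzymatic digestion and sorted by flow cytometry on Cx3cr1, a chemokine receptor of microglia, and libraries were made with the QIAseq FX single cell RNA library kit. The labels give 8 groups, sham and irradiated at 2 h, 6 h, 1 day and 1 week, with 6 animals each, so 48 libraries. Every animal gave 1 library, and each time point had its own sham animals. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, FastQC 0.11.8, STAR 2.6.1d and featureCounts 1.5.1 with builds GRCm38 and mm10; the annotation and the way reads were assigned to genes are not stated.

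The deposited table holds RPKM made by the authors for 48526 genes, 27654 of them above 0 in at least 1 library. Each of the 719081 values above 0 is a whole number of reads, within a tolerance of 0.001 reads, scaled by the distance from gene start to gene end (introns included) and by the total reads of a library. That total was in general not the library's own: it changed from gene to gene, and 2.05% of the values were divided by the total of their own library. Undoing the division gave whole reads for 100% of the values, and in 48 of 48 libraries the recovered reads summed to a total of the set, so each total was matched to its library. For 95 genes of at most 16 reads more than 1 match was possible. RPKM was then recomputed with each library's own total, and all results rest on these values unless they are named as deposited. Between the 5th and 95th percentile the deposited values were 0.436 to 3.11 times the recomputed ones. In simulated data the recovery was checked and returned 100% of the values. Because the gene span includes introns, levels are not comparable between genes, and the filter below leaves out many long genes.

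Total reads on genes ran from 175382 to 3856777 per library. Libraries with under 1000000 were sham 1 day library 6 (175382 reads), irradiated 2 h library 2 (395761) and sham 6 h library 4 (731819). The labels mention no molecular identifiers, so intervals given for a share of reads cover counting error only. In simulated data of the same size, limma called 33.7% to 40.2% of genes changed 2-fold and 57.9% to 64.9% of genes changed 4-fold, and 3.1% to 8.7% of its calls were unchanged genes. The simulated libraries of a group had no structure among them such as that seen in the 6 h sham group below. These shares therefore do not cover calls that follow such structure.

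Genes with an RPKM of 1 or more in at least 6 libraries were kept (10132 genes). The 8 group means were fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with eBayes set to trend and robust (40 residual degrees of freedom). Each time point's irradiated minus sham contrast, the 3 differences of this effect between adjacent times, an F test of these 3 differences and an F test of the sham groups over time were taken from the same fit. Tests are two-sided, and adjusted p values are Benjamini-Hochberg values over the genes of a contrast with a threshold of 0.05. Overlaps of called genes between times were tested with one-sided Fisher exact tests, adjusted over 12.

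The 29 gene lists, written before the data were examined like the tests above, cover p53 targets, DNA damage and repair, S phase, mitosis, homeostatic and disease-associated microglia, inflammatory and interferon genes, antigen presentation, complement and phagocytosis, lysosome, cholesterol synthesis and efflux, oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, histones, immediate early genes, the unfolded protein response and apoptosis. They also hold markers of neurons, neural progenitors, astrocytes, oligodendrocytes, endothelial and mural cells, perivascular macrophages, monocytes and neutrophils, lymphocytes and erythrocytes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a time point. The version with an estimated correlation stands beside it for the main fit and was not run for the alternatives. In a test added after seeing the data, the summed reads of each list per 1000000 reads on genes (RPM) were compared with exact two-sided permutation tests of 6 against 6 libraries, adjusted over 116 tests; 0.00216 is the smallest p such a test can give.

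The genes named were fixed by rule. For each time they are the 10 largest rises and 10 largest falls past the threshold with a mean RPKM of at least 5 in the higher group. Genes whose symbols mark them as predicted, small RNA or mitochondrial were left out, so small RNA genes with other symbols could remain. For each list the named genes are up to 4 members with the smallest adjusted p, or up to 2 with the highest mean where none passed. For the differences between times and the sham F test they are the 10 with the smallest adjusted p. A panel of 21 genes is given at every time whatever its result. Of the panel, Mki67, Top2a and Ccnb1 did not reach the RPKM filter and are given in RPM and from limma voom.

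Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, array weights, leaving out libraries of outlying detection, each time point alone, and the replicate number as a block. Alternatives chosen after seeing the data were the RPKM exactly as deposited, voom on the recovered reads (10 or more reads in at least 6 libraries), leaving out libraries under 1000000 reads, setting sham 6 h libraries 1 to 4 apart, and removing each library's trend with transcript GC content and length (10099 genes). Figures and list sums were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.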

Results

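The series follows hippocampal microglia of juvenile mice over the first week after whole brain irradiation. Changes below are irradiated minus sham on the log2(RPKM + 1) scale with their standard error after ±, RPKM values carry the SD, and every group has n = 6 animals. Adjusted p values are from limma over 10132 genes. The labels do not say whether the library kit marks the strand, so values of genes that overlap another gene or have close paralogs are uncertain. Of the 205 genes named, 81 share positions with another gene. For 43, with P2ry12, Ctsb, Cxcl10 and Cx3cr1 among them, that gene is not a predicted or small RNA gene.

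The largest component of variation, with 15.4% of the variance, did not follow irradiation alone. Sham 6 h libraries 1 to 4 lay with the 2 h libraries on it, and sham 6 h libraries 5 and 6 lay with the irradiated 6 h and the later libraries. The gap between them was 47.4 of a total range of 77.5. Between these sets, 564 genes were higher and 330 lower in libraries 5 and 6. The third component, with 5.9%, had the 2 h, 6 h and 1 day irradiated libraries at 6.67 and above and the sham libraries at 6.47 and below, without a gap between them, and the irradiated 1 week libraries lay among the sham. On the second component, with 7.19%, the irradiated 1 week libraries lay at -31.55 to -11.14 and the sham 1 week libraries at -6.38 to 19.95. Results at 6 h are therefore given with all 6 sham libraries and with libraries 5 and 6 alone. List p values with libraries 5 and 6 alone are from camera at the preset correlation, without the version with an estimated correlation. They are not to be read as stronger than those with all 6.

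**Figure D1:**
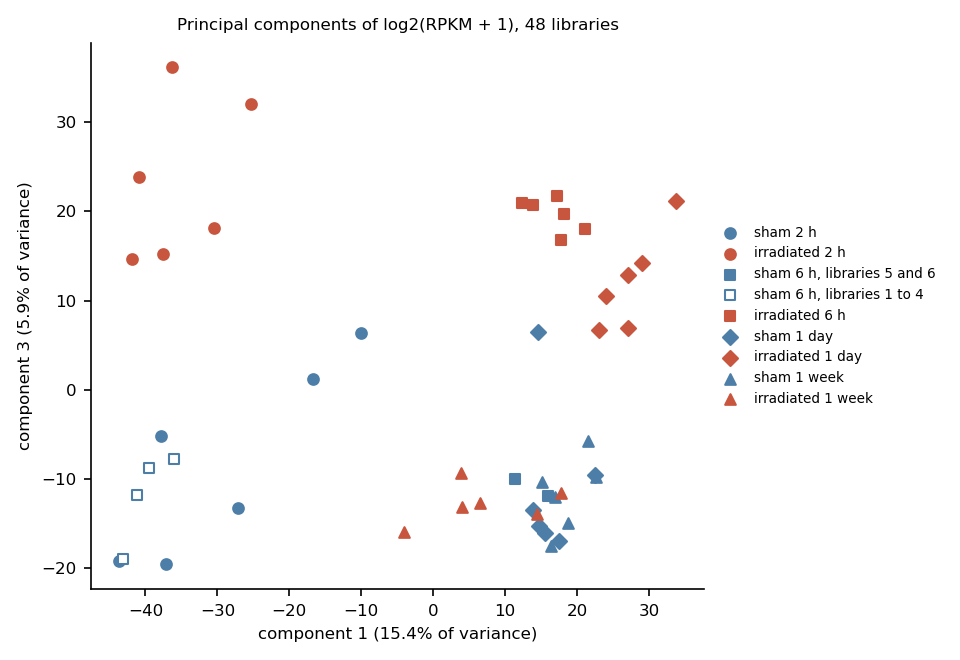
Position of the 48 libraries on principal component 1 (15.4% of the variance) and component 3 (5.9%) of log2(RPKM + 1), 1 point per library; shape gives the time and colour the treatment, and the open squares are sham 6 h libraries 1 to 4. These 4 libraries lie with the 2 h libraries on component 1, while sham 6 h libraries 5 and 6 lie with the irradiated 6 h libraries.

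At 2 h after irradiation, targets of p53 and genes of inflammation rose. Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases (ENSMUSG00000023067, GRCm38 chromosome 17, 29090979 to 29100722), went from 1.81 ± 1.43 to 124 ± 26.7 RPKM, a change of 5.58 ± 0.25 (adjusted p = 1.16e-21). Cxcl10, a chemokine that draws T cells, went from 4.75 ± 4.56 to 248 ± 95.5 RPKM, a change of 5.76 ± 0.43 (adjusted p = 4.21e-14). The other 8 of the 10 largest rises were Phlda3, an inhibitor of Akt signalling (4.38 ± 0.18), the kinase Plk2 (3.99 ± 0.24), the pro-apoptotic Pmaip1 (3.70 ± 0.29), and the stress protein Sesn2 (3.69 ± 0.25). They also held cyclin G1 or Ccng1 (3.54 ± 0.12), the thiamine transporter Slc19a2 (3.44 ± 0.17), Trp53inp1 (3.38 ± 0.16) and the chemokine Cxcl16 (3.25 ± 0.26). Each of these 10 was higher in 6 of 6 irradiated libraries than in every sham library. The 10 largest falls were smaller: Mt1, a metallothionein (-1.35 ± 0.37), the transcription factor Maf (-1.33 ± 0.14), Dph3 (-1.29 ± 0.41), Pomk (-1.28 ± 0.30), the histone gene Hist3h2a (-1.25 ± 0.33) and Fam46a (-1.24 ± 0.18). They went on with Zbtb45 (-1.21 ± 0.37), the orphan receptor Gpr165 (-1.21 ± 0.32), Sft2d2 (-1.15 ± 0.20) and Ighm, the immunoglobulin mu heavy chain (-1.13 ± 0.16). Maf, Hist3h2a, Fam46a, Sft2d2 and Ighm were lower in 6 of 6 irradiated libraries than in every sham library.

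Of the 32 measured p53 targets, 26 rose, 1 fell and 5 did not pass at 2 h (26 and 1 adjusted over the list alone). The 32 as a list had camera adjusted p = 4.09e-73, and adjusted p = 5.53e-13 with an estimated correlation. Mdm2, the ubiquitin ligase that targets p53, rose by 2.96 ± 0.16 and the pro-apoptotic Bax by 2.12 ± 0.34. The member that fell was Sesn1 (-0.39 ± 0.12), named after its values were seen. Of 26 inflammatory genes 14 rose and 0 fell (15 and 1 adjusted over the list alone; 12 did not pass). The 26 as a list had adjusted p = 2.68e-21, and adjusted p = 0.000645 with an estimated correlation. They included the pattern receptor Tlr2 (2.56 ± 0.16), the adhesion molecule Icam1 (1.74 ± 0.17), and the cytokines Tnf (3.04 ± 0.45), Il1b (1.49 ± 0.29) and Ccl2 (1.48 ± 0.30); Ccl3 did not pass (0.47 ± 0.36). Of 17 antigen presentation genes 8 rose (8 rose and 1 fell adjusted over the list alone). The 17 as a list had adjusted p = 9.6e-05, and adjusted p = 0.0371 with an estimated correlation. Tap1, a peptide transporter, rose by 2.10 ± 0.20, and the class I genes H2-Q4 by 1.85 ± 0.31 and H2-K1 by 1.43 ± 0.25. The co-stimulatory Cd80, also on the p53 list, rose by 0.79 ± 0.12 and Cd74, the class II invariant chain, by 1.65 ± 0.35. The class II gene H2-Aa did not pass (0.06 ± 0.29). Interferon-stimulated genes rose in 8 of 28 members (8 adjusted over the list alone). The 28 as a list had adjusted p = 1.98e-05, but adjusted p = 0.105 with an estimated correlation. Parp14 was at 1.06 ± 0.14, Ifit3 at 1.08 ± 0.28, Ifit1 at 0.77 ± 0.19 and Gbp2 at 0.75 ± 0.21. In a test chosen after seeing the data, here and at the other times, the reads on a list were summed per 1000000 reads on genes (RPM). Reads on the interferon-stimulated genes list were 1599 to 2064 RPM in irradiated libraries 1 to 3, 808 to 1099 in irradiated libraries 4 to 6 and 705 to 1095 in sham libraries (exact permutation adjusted p = 0.134).

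Of 25 homeostatic microglia genes 1 rose, 7 fell and 17 did not pass at 2 h (1 and 10 adjusted over the list alone). The 25 as a list had adjusted p = 9.15e-05, and adjusted p = 0.00983 with an estimated correlation. The purinergic receptor gene P2ry12 fell by 0.60 ± 0.13 on the log2 scale, Gpr34 by 0.57 ± 0.12, Golm1 by 0.63 ± 0.13 and the transcription factor Sall1 by 0.70 ± 0.18, while P2ry6, a receptor for UDP, rose by 0.72 ± 0.12. Tmem119 (0.18 ± 0.19) and the sorting marker Cx3cr1 (-0.22 ± 0.09) did not pass. Of 19 apoptosis genes 4 rose and 1 fell (6 and 1 adjusted over the list alone). The 19 as a list had adjusted p = 0.0199, and adjusted p = 0.0371 with an estimated correlation. The apoptosome gene Apaf1 (1.14 ± 0.09) and the anti-apoptotic Bcl2l1 (0.64 ± 0.17) rose, while the pro-apoptotic Bid fell by 0.60 ± 0.13. Apaf1 and Bax (2.12), which rose too, are also on the p53 list. Of 18 complement and phagocytosis genes 2 rose and 2 fell (4 and 3 adjusted over the list alone). The 18 as a list had adjusted p = 0.371. The receptors C3ar1 (1.16 ± 0.12) and C5ar1 (1.38 ± 0.20) rose, and Trem2 (-0.52 ± 0.17) and Fcgr2b (-0.47 ± 0.13) fell. Of 26 disease-associated microglia genes 4 rose and 1 fell (5 and 2 adjusted over the list alone). The disease-associated list had adjusted p = 0.077. Lilrb4a was at 1.05 ± 0.20, Cd9 at 0.59 ± 0.12, B2m at 0.72 ± 0.15 and Clec7a at 0.59 ± 0.19. Apoe (0.31 ± 0.27) and Cst7 (0.16 ± 0.18) did not pass.

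In all, 873 genes changed at 2 h, 466 up and 407 down, and with a pseudocount of 0.1 443 up and 455 down. The share of reads on mitochondrial genes was 10.5% ± 3.03 in the irradiated and 5.93% ± 2.49 in the sham libraries. Nearly all of it was 1 mitochondrial ribosomal RNA, mt-Rnr2, with 5.86% to 14.1% of reads in irradiated and 2.84% to 9.02% in sham libraries. Fitted alone, the 12 libraries of this time gave 542 genes, and the values exactly as deposited gave 52.

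**Figure D2:**
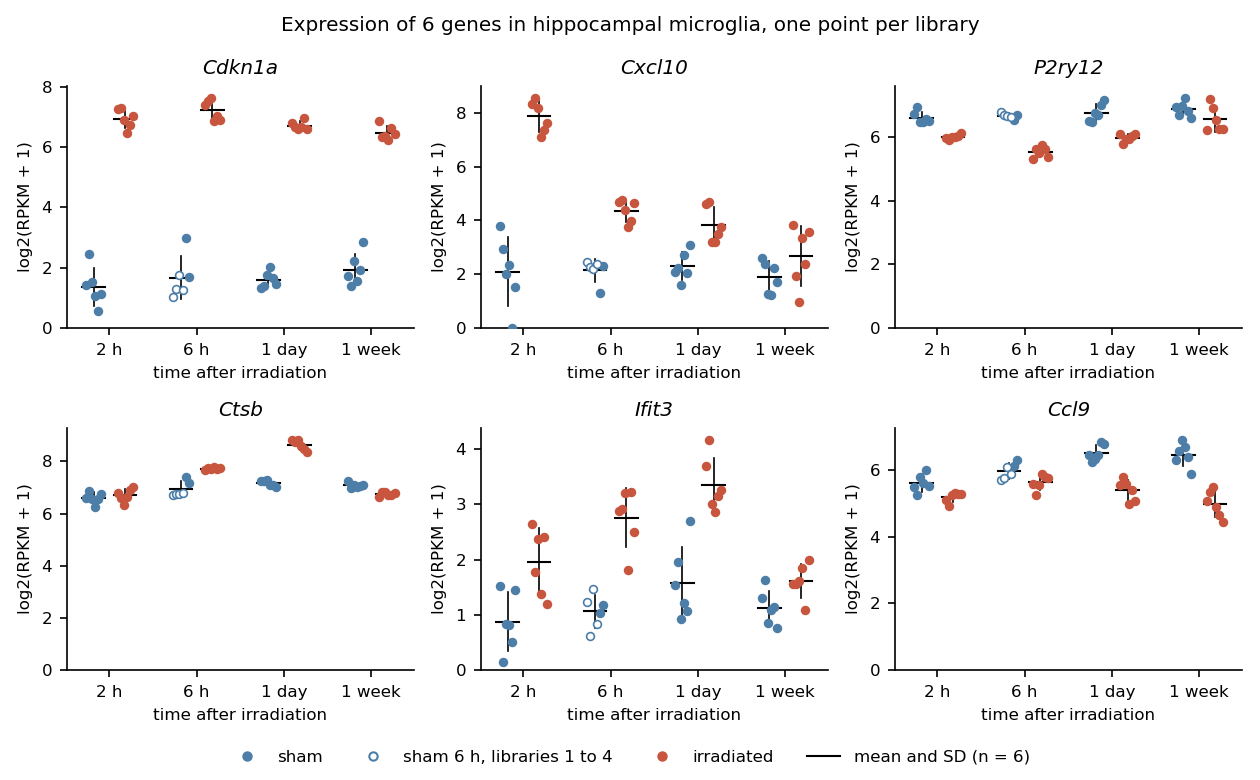
Expression of Cdkn1a, Cxcl10, P2ry12, Ctsb, Ifit3 and Ccl9 as log2(RPKM + 1) against time after irradiation, 1 point per library, with horizontal lines at the mean and vertical lines of 1 SD (n = 6); open points are sham 6 h libraries 1 to 4. Cdkn1a is higher in 6 of 6 irradiated libraries than in every sham library at each time, and Ccl9 at 1 week is lower in 6 of 6.

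At 6 h, the p53 targets stayed high with either set of sham libraries. Cdkn1a went from 2.59 ± 2.22 to 152 ± 35.9 RPKM, a change of 5.55 ± 0.25 with all 6 sham libraries and 4.88 with libraries 5 and 6 alone (adjusted p = 9.01e-22 and 3.84e-15). The same 2 values were 5.11 and 4.99 for Gdf15, a stress cytokine of the TGF-beta family, 4.19 and 4.26 for Phlda3, 4.16 and 2.88 for the reductase Dcxr, and 3.95 and 3.81 for the microtubule regulator Psrc1. The values were 3.84 and 3.82 for the matrix protein gene Matn1, 3.60 and 2.32 for Bax, 3.49 and 3.60 for Ccng1, 3.41 and 2.68 for Sesn2, and 2.98 and 2.68 for Fndc10, and all 10 passed both ways. Of the 10 largest falls, 3 passed both ways: Gpr165 (-2.78 and -1.53), the fructose transporter Slc2a5 (-1.44 and -1.501) and Hpgd, which breaks down prostaglandins (-1.38 and -0.93). The other 7 passed with all 6 sham libraries only: AF357399 (-2.15 and -2.16), the transcription factor Cebpd (-1.78 and -0.32) and the linker histone Hist1h1d (-1.69 and -1.47). With them were Lpar6 (-1.67 and -0.19), Mblac1 (-1.505 and -0.65), Galnt1 (-1.39 and -0.17) and Fcrl1 (-1.36 and -0.87).

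Of the 32 p53 targets 26 rose and 1 fell at 6 h (26 and 1 adjusted over the list alone). The 32 as a list had adjusted p = 4.56e-39, and adjusted p = 5.04e-09 with an estimated correlation. With libraries 5 and 6 alone 23 of them rose and 1 fell (adjusted p = 2.54e-79). Mdm2 rose by 1.71 ± 0.16 and by 1.87 with libraries 5 and 6. Of 25 homeostatic genes 4 rose and 12 fell (4 and 14 adjusted over the list alone). The 25 as a list had adjusted p = 5.55e-05, and adjusted p = 0.0128 with an estimated correlation. With libraries 5 and 6 alone 1 of them rose and 4 fell (adjusted p = 3.69e-09, preset correlation only). P2ry12 went from 99.5 ± 5.91 to 45.2 ± 5.08 RPKM, a change of -1.13 ± 0.13 and of -1.08 with libraries 5 and 6, and P2ry6 rose by 0.99 ± 0.12 and 0.56. Gpr34 (-0.89 and -0.50) and Sall1 (-0.87 and -0.60) passed with all 6 sham libraries only, and Cx3cr1 (-0.24 and -0.24) and Tmem119 (0.25 and 0.05) did not pass.

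Inflammatory genes rose in 13 of 26 members at 6 h and fell in 0 (15 and 0 adjusted over the list alone). The 26 as a list had adjusted p = 8.43e-05, but adjusted p = 0.167 with an estimated correlation. With libraries 5 and 6 alone 8 rose (adjusted p = 3.08e-09). Tnf rose by 2.76 ± 0.45 and 2.61. Among chemokines Ccl4 rose by 2.34 ± 0.36 and 2.12 and Ccl12 by 2.21 ± 0.30 and 1.75. Ccl3 rose by 2.15 ± 0.36 and 1.95, Cxcl16 by 1.75 ± 0.26 and 1.83 and Ccl2 by 1.41 ± 0.30 and 1.95. Il1b (0.79 ± 0.29 and 0.32) passed with all 6 sham libraries only. Interferon-stimulated genes rose in 16 of 28 (18 adjusted over the list alone). The 28 as a list had adjusted p = 6e-06, but adjusted p = 0.117 with an estimated correlation. Those called with libraries 5 and 6 alone were 2, Ifit3 (1.70 ± 0.28 and 1.65) and Ifit1 (0.92 ± 0.19 and 0.99), with adjusted p = 1.41e-10 for the list. Bst2 (2.48 and 1.41) and Zbp1 (1.14 and 0.88) passed with all 6 only. Antigen presentation genes rose in 7 of 17 (9 adjusted over the list alone). The 17 as a list had adjusted p = 0.000734, but adjusted p = 0.0913 with an estimated correlation. With libraries 5 and 6 alone 4 rose (adjusted p = 0.0104). H2-K1 rose by 1.78 ± 0.25 and 1.80, H2-D1 by 1.28 ± 0.24 and 1.25 and Tap1 by 1.14 ± 0.20 and 1.07. Cd74 (2.15 ± 0.35 and 1.68) passed with all 6 only, and H2-Aa (-0.07 ± 0.29 and -0.84) did not pass.

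Disease-associated microglia genes at 6 h rose in 15 of 26 and fell in 1 (16 and 1 adjusted over the list alone). The 26 as a list had adjusted p = 3e-06, but adjusted p = 0.0542 with an estimated correlation. With libraries 5 and 6 alone 2 rose and 1 fell (adjusted p = 0.000141). The growth factor Csf1 rose by 2.09 ± 0.30 and 1.78 and the tetraspanin Cd9 by 0.82 ± 0.12 and 0.68. Ctsb (0.79 and 0.43), Cd68 (0.96 and 0.28), Cst7 (0.61 and 0.46) and Apoe (0.97 and 0.18) passed with all 6 only. Lysosomal genes rose in 13 of 29 and fell in 4 (13 and 6 adjusted over the list alone). The 29 as a list had adjusted p = 0.00947, but adjusted p = 0.167 with an estimated correlation. Libraries 5 and 6 alone gave 1 in each direction (adjusted p = 0.136). Beta-glucuronidase, Gusb, rose by 1.18 ± 0.10 and 1.04, while Ctsz (1.15 and 0.60) and Ctsa (0.98 and 0.32) passed with all 6 only. Complement and phagocytosis genes rose in 8 of 18 and fell in 4 (8 and 5 adjusted over the list alone). The 18 as a list had adjusted p = 0.107. Of them 3 rose and 1 fell with libraries 5 and 6 alone (adjusted p = 0.339). The receptors C3ar1 (1.37 ± 0.12 and 1.24) and C5ar1 (1.86 ± 0.20 and 1.73) passed both ways, and C1qb (1.39 ± 0.24 and 0.01) and Gas6 (1.11 ± 0.21 and 0.52) did not. Ribosomal protein genes rose in 30 of 81 and fell in 1 (33 and 1 adjusted over the list alone). The 81 as a list had adjusted p = 5.67e-06, but adjusted p = 0.0913 with an estimated correlation. Libraries 5 and 6 alone left 2, Rps19 (1.86 and 1.02) and the p53 target Rps27l (1.46 and 1.82), with adjusted p = 0.000324 for the list. Rps2 (1.11 and 0.74) and Rpl32 (1.70 and 0.66) passed with all 6 only.

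In all, 2120 genes changed at 6 h, 1309 up and 811 down (61.7% up), and with libraries 5 and 6 alone 208, 157 up and 51 down, 193 of them shared in direction. Removing the GC content and length trend gave 714 up and 768 down (48.2% up). Any 2 of the 6 sham libraries as controls gave 208 to 2113 genes over 15 pairs, with a median of 498 and the lowest count from libraries 5 and 6. Pairs within libraries 1 to 4 gave 1960 to 2113 genes, and pairs of 1 of these with library 5 or 6 gave 424 to 561. Of the 2120 genes 92.7% kept their sign with libraries 5 and 6 alone. The median ratio of that effect to the effect with all 6 was 0.51, and 1.012 for the called p53 targets.

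**Figure D3:**
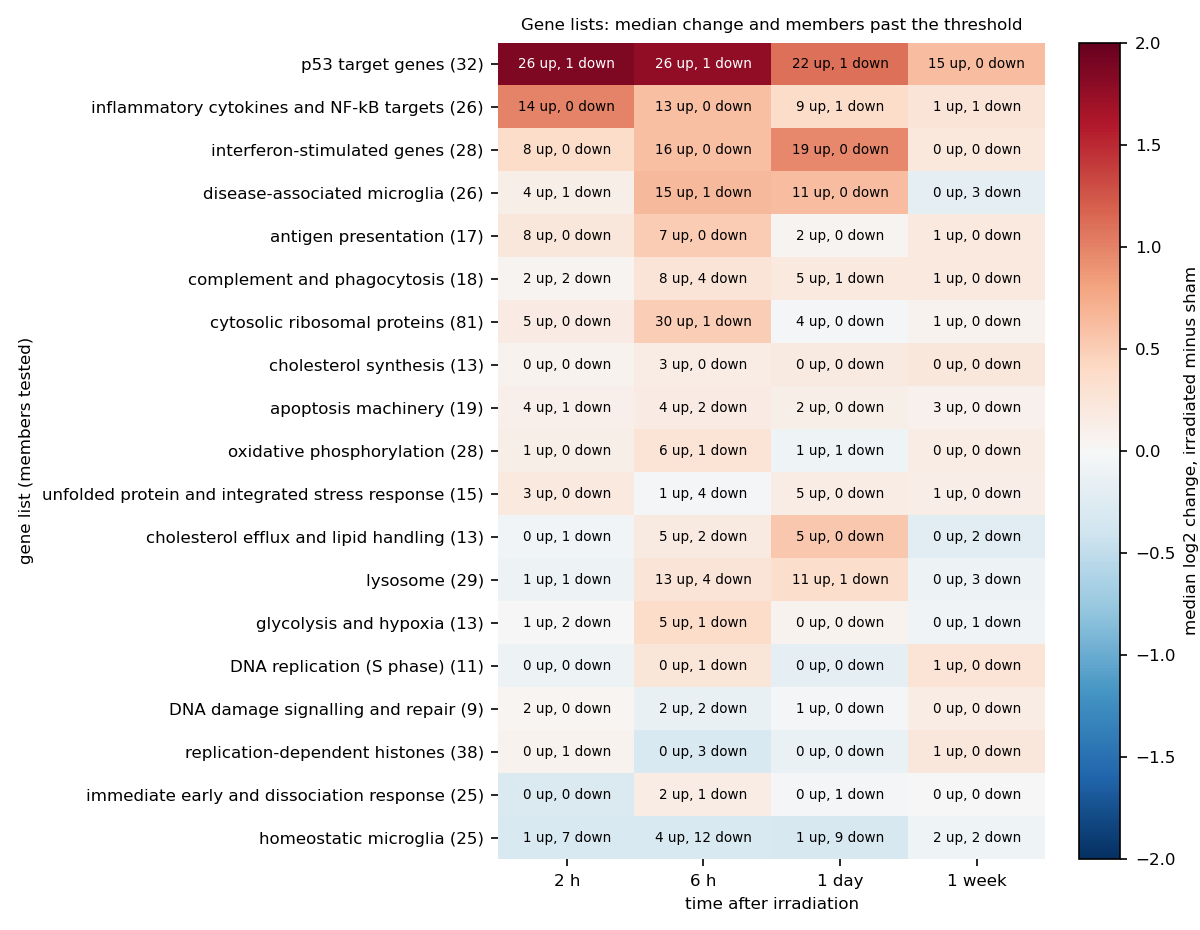
Median log2 change (colour, irradiated minus sham) of the 19 gene lists with at least 5 tested members at 4 times, with the number of members past the threshold in each direction (up or down) in each cell; the members tested are in brackets and the 6 h column uses all 6 sham libraries. The p53 targets have 26, 26, 22 and 15 members up at 2 h, 6 h, 1 day and 1 week, and the interferon-stimulated genes 8, 16, 19 and 0.

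At 1 day, disease-associated, lysosomal and interferon-stimulated genes were high together with p53 targets, and homeostatic genes were low. Cathepsin B, Ctsb, on both the disease-associated and the lysosome list, went from 143 ± 11.1 to 398 ± 54.6 RPKM. This was a change of 1.46 ± 0.11 (adjusted p = 8.65e-14). Ifit3, an interferon-induced gene, went from 2.26 ± 1.73 to 9.75 ± 4.05 RPKM, a change of 1.79 ± 0.28 (adjusted p = 1.09e-05). Cdkn1a went from 2.08 ± 0.573 to 104 ± 11.2 RPKM (5.11 ± 0.25). The rest of the 10 largest rises were Zakit (3.48 ± 0.62), Psrc1 (3.21 ± 0.18), Phlda3 (3.14 ± 0.18), Ccng1 (2.81 ± 0.12) and Bax (2.55 ± 0.34). With them were Fndc10 (2.52 ± 0.37), galectin 1 or Lgals1 (2.49 ± 0.26), Sesn2 (2.42 ± 0.25) and osteopontin or Spp1 (2.29 ± 0.24). Each of the 10 was higher in 6 of 6 irradiated libraries than in every sham library. The 10 largest falls were the immunoglobulin segment Ighj1 (-4.34 ± 0.89), the class II accessory gene H2-Oa (-1.91 ± 0.45), Gpr165 (-1.71 ± 0.32), Wdr24 (-1.68 ± 0.50) and Mycl (-1.62 ± 0.27). They went on with Smim10l2a (-1.36 ± 0.33), Crybb1 (-1.32 ± 0.28), Socs3, an inhibitor of cytokine signalling (-1.29 ± 0.29), Thap11 (-1.25 ± 0.27) and Lst1 (-1.25 ± 0.32). Of these Gpr165, Crybb1 and Socs3 were lower in 6 of 6.

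Of 28 interferon-stimulated genes 19 rose and 0 fell at 1 day (27 and 0 adjusted over the list alone). The 28 as a list had adjusted p = 1.09e-30, and adjusted p = 3.6e-05 with an estimated correlation. Trim30a was at 0.97 ± 0.10, Slfn2 at 1.86 ± 0.28 and viperin, Rsad2, at 1.78 ± 0.27. Reads on this list were 1053 ± 109 RPM in sham and 2763 ± 383 in irradiated libraries, higher in 6 of 6 (exact permutation p = 0.00216, adjusted p = 0.00897). Markers of monocytes and neutrophils were at 25.0 ± 13.2 and 51.1 ± 24.8 RPM (exact permutation p = 0.0433, adjusted p = 0.0985), with Plac8 up by 0.79 ± 0.21. Of 26 disease-associated genes 11 rose and 0 fell (16 and 1 adjusted over the list alone). The 26 as a list had adjusted p = 4.73e-19, and adjusted p = 6.83e-05 with an estimated correlation. Lipoprotein lipase, Lpl, was at 1.89 ± 0.20, galectin 3, Lgals3, at 1.503 ± 0.18 and Cst7 at 1.15 ± 0.18. Apoe did not pass (0.42 ± 0.27). Of 29 lysosomal genes 11 rose and 1 fell (15 and 1 adjusted over the list alone). The 29 as a list had adjusted p = 2.35e-11, and adjusted p = 0.000204 with an estimated correlation. Gusb (0.84 ± 0.10), cathepsin C, Ctsc (0.75 ± 0.10), and the membrane protein gene Lamp1 (0.56 ± 0.10) rose. Of 13 cholesterol efflux and lipid genes 5 rose (7 adjusted over the list alone). The 13 as a list had adjusted p = 4.08e-07, and adjusted p = 0.000454 with an estimated correlation. With Lpl, which is also on the disease-associated list, the lipid droplet gene Plin2 (1.04 ± 0.19) and the cholesterol transporters Abca1 (0.70 ± 0.13) and Abcg1 (0.85 ± 0.19) rose.

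Of 25 homeostatic genes 1 rose and 9 fell at 1 day (1 and 11 adjusted over the list alone). The 25 as a list had adjusted p = 1.75e-10, and adjusted p = 3.6e-05 with an estimated correlation. Siglech changed by -1.12 ± 0.11, P2ry12 by -0.79 ± 0.13 and Slc2a5 by -0.98 ± 0.17. The membrane gene Upk1b changed by -0.80 ± 0.14, Sall1 by -0.78 ± 0.18 and Cx3cr1 by -0.42 ± 0.09, while Tmem119 did not pass (-0.39 ± 0.19). Of 32 p53 targets 22 rose and 1 fell (23 and 1 adjusted over the list alone). The 32 as a list had adjusted p = 2.89e-44, and adjusted p = 9.4e-10 with an estimated correlation. Mdm2 rose by 1.43 ± 0.16. Inflammatory genes rose in 9 of 26 and fell in 1 (12 and 1 adjusted over the list alone). The 26 as a list had adjusted p = 8.74e-07, but adjusted p = 0.0518 with an estimated correlation. Ccl12 rose by 2.12 ± 0.30, Ccl2 by 1.86 ± 0.30 and Tnf by 1.85 ± 0.45. Ccl7 rose by 1.70 ± 0.37, Cxcl16 by 1.39 ± 0.26 and Il1b by 1.27 ± 0.29, while Ccl3 did not pass (1.15 ± 0.36). Complement and phagocytosis genes rose in 5 of 18 and fell in 1 (5 and 1 adjusted over the list alone). The 18 as a list had adjusted p = 0.00684, and adjusted p = 0.0498 with an estimated correlation. C3ar1 rose by 1.48 ± 0.12, C5ar1 by 1.46 ± 0.20, the phagocytic receptor Axl by 0.99 ± 0.15 and its ligand Gas6 by 1.00 ± 0.21. Genes of the unfolded protein and integrated stress response rose in 5 of 15 (7 adjusted over the list alone). The 15 as a list had adjusted p = 1.41e-05, and adjusted p = 0.00365 with an estimated correlation. The serine synthesis gene Psat1 was at 1.00 ± 0.13 and the chaperones Hsp90b1 at 0.80 ± 0.12 and Calr at 0.69 ± 0.12. Sesn2 (2.42), also on the p53 list, was among the 5 that rose. Of antigen presentation genes 2 of 17 rose (3 adjusted over the list alone). The 17 as a list had adjusted p = 0.325. Tap1 rose by 0.93 ± 0.20 and Cd80, also on the p53 list, by 0.56 ± 0.12. Cd74 (-0.14 ± 0.35) and H2-Aa (-0.70 ± 0.29) did not pass.

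In all, 435 genes changed at 1 day, 294 up and 141 down. The sham group holds the shallowest library, and without the 3 libraries of the lowest depth 511 genes changed. Array weights gave 743 genes, voom 690, and the 12 libraries alone 254.

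At 1 week, p53 targets were still high, the chemokines Ccl9 and Ccl6 were low while Ccl2 was still high, and cell cycle genes were high. Cdkn1a went from 3.08 ± 1.67 to 89.4 ± 15.2 RPKM, a change of 4.54 ± 0.25 (adjusted p = 1.25e-17). The chemokine Ccl9 went from 89.0 ± 21.0 to 31.5 ± 8.91 RPKM, a change of -1.48 ± 0.16 (adjusted p = 2.16e-08), and was lower in 6 of 6. It had already fallen at 1 day (-1.12 ± 0.16, adjusted p = 3.94e-06, lower in 6 of 6) and was at -0.42 ± 0.16 at 2 h and -0.34 ± 0.16 at 6 h, which did not pass. The other large rises were Tcf19, a gene of the G1/S transition (2.90 ± 0.86), Phlda3 (2.67 ± 0.18), Fndc10 (2.37 ± 0.37), and Lars2 (2.03 ± 0.52). The list of 10 went on with the receptor kinase Epha2 (2.02 ± 0.21), Dcxr (1.92 ± 0.36), Ccng1 (1.64 ± 0.12), Sesn2 (1.54 ± 0.25) and Mxra8 (1.53 ± 0.39). Lars2 shares sequence with a mitochondrial ribosomal RNA, and mitochondrial genes took 3.31% ± 0.685 of the reads in irradiated and 1.81% ± 0.335 in sham libraries. Its value is therefore uncertain. The other large falls were the chemokine Ccl6 (-1.63 ± 0.28), cystatin C or Cst3 (-1.35 ± 0.37), Atf6b (-1.19 ± 0.32), Fam210b (-1.11 ± 0.25) and C1qbp (-1.05 ± 0.24). So were Vhl, which marks hypoxia factors for breakdown (-1.04 ± 0.22), the endotoxin receptor Cd14 (-0.97 ± 0.25), Ywhae (-0.94 ± 0.24) and Efhd2 (-0.92 ± 0.20).

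Reads on the mitosis list were 99.6 ± 22.0 RPM in sham and 229 ± 31.4 in irradiated libraries at 1 week, 2.30 times as many and higher in 6 of 6 (exact permutation p = 0.00216, adjusted p = 0.00897). Reads on the S phase list were 332 ± 30.1 and 633 ± 354, higher in 6 of 6 (exact permutation p = 0.00216, adjusted p = 0.00897). Irradiated library 4 stood at 1348 and the other 5 between 418 and 560. At this depth few of these genes reach the RPKM filter. Of the 3 mitosis genes tested by limma 0 passed (1 at an unadjusted p under 0.05), and limma voom, which keeps 21, called 12 up (adjusted p = 4.12e-09 for the list). Of 11 S phase genes 1 rose, the helicase gene Mcm6 by 0.75 ± 0.14 (2 adjusted over the list alone). The 11 as a list had adjusted p = 0.0186, but adjusted p = 0.11 with an estimated correlation. Voom called 9 of 26. By voom the proliferation marker Mki67 rose by 2.31 ± 0.495 (adjusted p = 0.00211), from 8.27 to 27.6 RPM, and the topoisomerase gene Top2a by 2.32 ± 0.540 (adjusted p = 0.0047), from 4.92 to 18.3. Cyclin B1, Ccnb1, had 9 reads in the sham and 64 in the irradiated libraries. Markers of neural progenitors, which also divide, were at 84.8 ± 38.6 and 118 ± 165 RPM (exact permutation p = 0.961, adjusted p = 0.969). Those of perivascular macrophages were at 774 ± 112 and 1267 ± 189 RPM, higher in 6 of 6 (exact permutation adjusted p = 0.00897), mostly through Stab1 (676 ± 119 and 1156 ± 197 RPM). Earlier, mitosis list reads in sham and irradiated libraries were 77.7 and 53.1 RPM at 2 h, 78.4 and 48.4 at 6 h and 65.4 and 43.4 at 1 day. None of these sums passed (exact permutation adjusted p = 0.161, 0.0695 and 0.123). By voom 0 of 21 members passed at these times, and the list had adjusted p = 0.212 at 2 h, 0.0716 at 6 h and 0.035 at 1 day, with a median change of -0.832 at 1 day. Mki67 and Top2a had 61 and 42 reads in sham against 33 and 41 in irradiated libraries at 2 h. They had 81 and 64 against 19 and 21 at 6 h, and 19 and 32 against 0 and 7 at 1 day.

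**Figure D4:**
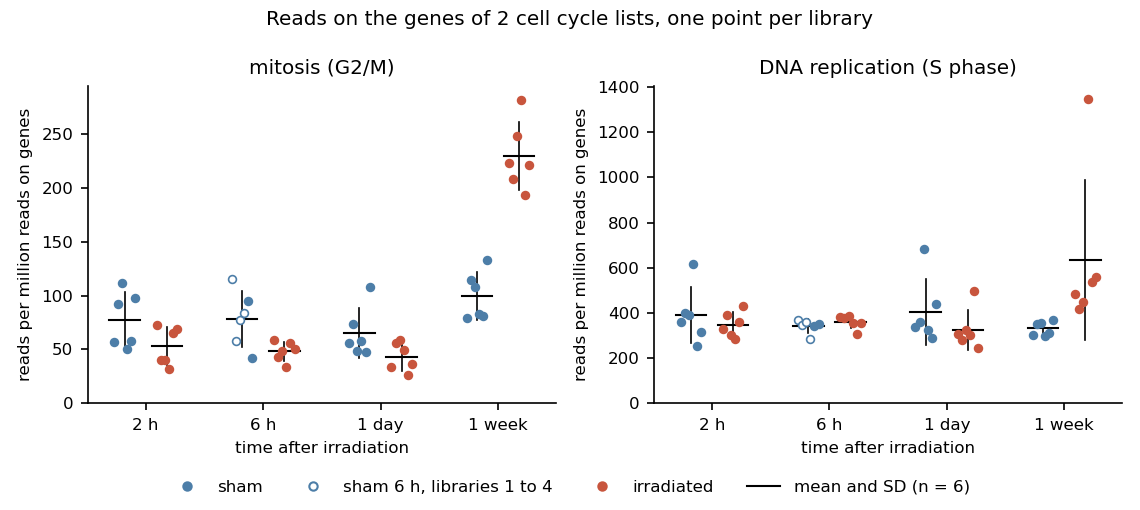
Reads on the mitosis list and on the S phase list in RPM against time after irradiation, 1 point per library, with horizontal lines at the mean and vertical lines of 1 SD (n = 6); open points are sham 6 h libraries 1 to 4. At 1 week the mean of the mitosis list is 99.6 in sham and 229 in irradiated libraries, and 6 of 6 irradiated libraries lie above every sham library on both lists.

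Of 32 p53 targets 15 rose and 0 fell at 1 week (22 and 0 adjusted over the list alone). The 32 as a list had adjusted p = 2.23e-24, and adjusted p = 1.44e-06 with an estimated correlation. Psrc1 was at 1.73 ± 0.18, Bax at 1.15 ± 0.34 and Mdm2 at 0.81 ± 0.16. Disease-associated genes fell in 3 of 26 and rose in 0 (6 and 1 adjusted over the list alone). The disease-associated list had adjusted p = 0.000876, but adjusted p = 0.258 with an estimated correlation. Those that fell were Ccl6, Ank (-0.53 ± 0.11) and the lectin receptor Clec7a (-0.79 ± 0.19). Apoe (-0.22 ± 0.27) and Cst7 (-0.11 ± 0.18) did not pass. Of 25 homeostatic genes 2 rose and 2 fell (2 and 4 adjusted over the list alone). The 25 as a list had adjusted p = 0.313. Fcrls rose by 0.72 ± 0.17 and Tmem119 by 0.65 ± 0.19, and Cst3 was among those that fell. Summed reads on the list were 147000 RPM in sham and 97670 in irradiated libraries, lower in 6 of 6 (exact permutation adjusted p = 0.00897), and Cst3 alone took 8.58% and 3.43% of all reads. P2ry12 (-0.31 ± 0.13), Sall1 (0.42 ± 0.18) and Cx3cr1 (0.10 ± 0.09) did not pass. Of 28 interferon-stimulated genes 0 passed by limma (0 adjusted over the list alone, and 7 at an unadjusted p under 0.05). The 28 as a list had adjusted p = 0.0637. Voom called 2 of 31. Ifitm3 was at 0.82 ± 0.55, Irf9 at -0.48 ± 0.23 and Ifit3 at 0.48 ± 0.28. Inflammatory genes rose in 1 and fell in 1 of 26 (5 and 1 adjusted over the list alone). The inflammatory list had adjusted p = 0.224. Ccl2 rose by 1.32 ± 0.30 and Cd14 fell. Tnf (1.38 ± 0.45), Il1b (0.22 ± 0.29) and Ccl3 (-0.30 ± 0.36) did not pass. Of antigen presentation genes Tap1 rose (0.86 ± 0.20; 1 of 17, and 2 rose and 1 fell adjusted over the list alone). The 17 as a list had adjusted p = 0.24. Cd74 (-0.63 ± 0.35) and H2-Aa (-0.17 ± 0.29) did not pass. Lysosomal genes fell in 3 of 29 (2 rose and 8 fell adjusted over the list alone). The 29 as a list had adjusted p = 0.0637. Lipa (-0.54 ± 0.15) and Lamp2 (-0.36 ± 0.10) were among them. Cholesterol efflux genes fell in 2 of 13 (4 adjusted over the list alone), again with adjusted p = 0.0637 for the list. They were Mylip (-0.51 ± 0.11) and Abcg1 (-0.74 ± 0.19).

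In all, 359 genes changed at 1 week, 206 up and 153 down (57.4% up), and with the GC content and length trend removed 157 up and 212 down (42.5% up). With scaling 174 were up and 178 down. Voom gave 931 genes, array weights 766, no filter 235 and the values as deposited 11.

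The size of the irradiation effect itself was compared between times. Of the genes that changed, with all 6 sham libraries at 6 h, 32 rose at all 4 times, 15 of them p53 targets. Of the 32, 27 had a smaller effect at 1 week than at 2 h. The 1 gene that fell at all 4 times was Klrd1, a receptor gene of natural killer cells (-0.87 ± 0.18 at 2 h), named after its values were seen. Effects that were smaller at 6 h than at 2 h were those of the adhesion molecule Vcam1 (3.10 at 2 h and 0.57 at 6 h; difference -2.53 ± 0.24), the NF-kB inhibitor Nfkbie (1.95 and -0.37), Donson (1.80 and -0.26), Tbc1d8 (1.31 and 0.14) and the carboxypeptidase Cpd (1.59 and 0.06). Vcam1 still passed at 6 h, and Cpd rose again at 1 day (1.01 ± 0.10). Effects that were larger at 6 h than at 2 h were those of Matn1 (3.84 against 1.39), Glipr2 (2.54 against 0.43), the epoxide hydrolase Ephx1 (2.00 against 0.26), the sulfatase Sulf2 (2.89 against 1.44) and Cep170b (1.83 against 0.64). These 10 differences passed with libraries 5 and 6 alone as well. From 6 h to 1 day the effect was lower for Gdf15 (5.11 to 1.70; difference -3.40 ± 0.49) and Gtse1 (2.34 to 0.71) and higher for Lpl (0.09 to 1.89), Ctsc (-0.21 to 0.75) and Hsp90b1 (-0.35 to 0.80), with either set of sham libraries. For Abca1 (-0.49 to 0.70) the difference did not pass with libraries 5 and 6 (adjusted p = 0.0725).

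From 1 day to 1 week the effects on single genes of the microglial lists differed, while the difference of a list as a whole was not tested. The effect on Ctsb went from 1.46 to -0.35 (difference -1.81 ± 0.15, adjusted p = 6.11e-11), on Spp1 from 2.29 to -0.45, on Lpl from 1.89 to -0.24, and on Lgals1 from 2.49 to -0.20. That on C3ar1 went from 1.48 to 0.09, and on the interferon-induced Dhx58 from 1.89 to -0.70 and Trim30a from 0.97 to -0.05. Cst7 (difference -1.26 ± 0.25, adjusted p = 0.0016) and Ifit3 (-1.31 ± 0.39, adjusted p = 0.0388) moved the same way. The effect on the homeostatic genes Siglech went from -1.12 to 0.07 (difference 1.19 ± 0.16), and those on Sall1 (1.2 ± 0.26), Tmem119 (1.04 ± 0.26) and Cx3cr1 (0.52 ± 0.13) rose as well, while that on P2ry12 did not pass (0.47 ± 0.18, adjusted p = 0.121). The effect on Ccng1 was lower by 1 week (-1.18 ± 0.16) and that on Cdkn1a did not pass (-0.57 ± 0.35, adjusted p = 0.372). The panel genes whose effect differed from 2 h to 6 h with all 6 sham libraries were Mdm2 (-1.25 ± 0.23), Bax (1.48 ± 0.48) and Ccl3 (1.68 ± 0.51). From 6 h to 1 day they were Cd74 (-2.29 ± 0.49), Ccng1 (-0.68 ± 0.16) and Phlda3 (-1.05 ± 0.25). None of these 6 passed with libraries 5 and 6 alone, where the differences were -1.085 for Mdm2, 0.205 for Bax, 1.475 for Ccl3, -1.82 for Cd74, -0.78 for Ccng1 and -1.12 for Phlda3.

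In numbers, the effect differed for 940 genes between 2 h and 6 h (563 up, 377 down), for 444 between 6 h and 1 day (173 up, 271 down), for 550 between 1 day and 1 week (257 up, 293 down) and for 1952 over the 4 times. With sham 6 h libraries 5 and 6 alone the first 2 counts were 75 (37 up, 38 down) and 31 (17 up, 14 down) and the last was 848. With the GC content and length trend removed the first 2 were 592 (282 up, 310 down) and 175 (93 up, 82 down). From 1 day to 1 week the majority turned without the libraries of low depth, without libraries of outlying detection (447 up, 400 down), with array weights (708 up, 628 down) and by voom (685 up, 581 down). With a pseudocount of 0.1 it turned as well (247 up, 245 down). Genes called in the same direction were shared by more than chance in 11 of 12 pairs of times and directions (one-sided Fisher exact tests). The tests take genes as independent, which they are not, and those with 6 h use all 6 sham libraries. As examples of such sharing, 215 rose at both 2 h and 6 h against 60.2 by chance, and 192 at both 6 h and 1 day against 38. The exception was falls at 1 day and 1 week (5 shared against 2.1 by chance, adjusted p = 0.0623). These passed with the GC content and length trend removed (14 against 4.2, adjusted p = 7.79e-05), with scaling (8 against 2.6, adjusted p = 0.00453) and by voom (17 against 9.1, adjusted p = 0.0105), but not with a pseudocount of 0.1 (4 against 2.5, adjusted p = 0.233). Genes that fell at 1 day but rose at 1 week numbered 12, more than the 5 that fell at both. They were 10 with the GC content and length trend removed, 9 with scaling, 31 by voom and 9 with a pseudocount of 0.1. Such opposite calls were not tested against chance. Across genes, which are not independent replicates, the effects at 1 day and 1 week had r = -0.083 and those at 6 h and 1 day r = 0.305.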

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

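Of the tests in this part, those of a wrong label, of progenitor reads, of the 6 h batch as the whole cause and of GC content for the interferon-stimulated genes were chosen after the result was seen. The comparisons with sham 6 h libraries 5 and 6 alone, with the GC content and length trend removed and without the libraries of low depth were also chosen after seeing the data.

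In 7 of 58 groups of 6 libraries, 1 library lay far from the other 5 by Dixon's test, which calls about 1 in 20 groups by chance. Intervals are 95% Wilson intervals. Sham 2 h library 5 had 2277000 reads on genes, against 1451000 to 1716000. For Cdkn1a, sham 2 h library 2 had an RPKM of 4.546 (others 0.4958 to 1.891) and sham 6 h library 5 one of 6.99 (others 1.032 to 2.419). S phase list reads in irradiated 1 week library 4 were 1348 RPM (3381 reads, interval 1304 to 1395), against 418.1 to 560. Progenitor and neuroblast reads were 159.2 RPM in sham 1 week library 4 (468 reads, interval 145.4 to 174.3), against 56.01 to 91.84. In irradiated 1 week library 3 they were 452.6 RPM (1274 reads, interval 428.4 to 478.1), against 30.35 to 88.1. Monocyte and neutrophil reads were 51.32 RPM in sham 1 day library 6 (9 reads, interval 27 to 97.53), against 15.38 to 23.28.

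The irradiation effect differed between times, by a test of the difference itself, for 940 genes between 2 h and 6 h, 444 between 6 h and 1 day, 550 between 1 day and 1 week and 1952 over the 4 times. From 2 h to 6 h the log2 differences of the 10 genes with the smallest p were Matn1 2.445, Glipr2 2.112, Ephx1 1.739, Sulf2 1.45, Cep170b 1.19, Cpd -1.529, Vcam1 -2.534, Tbc1d8 -1.17, Nfkbie -2.315 and Donson -2.058. From 6 h to 1 day they were Cep170b -1.223, Glipr2 -1.546, Sulf2 -1.004, Gdf15 -3.401, Gtse1 -1.626, Hsp90b1 1.149, Ctsc 0.958, Lpl 1.809, Cpd 0.942 and Abca1 1.19. From 1 day to 1 week they were Ctsb -1.81, C3ar1 -1.389, Dhx58 -2.591, Spp1 -2.733, Lpl -2.137, Smim3 -1.239, Lgals1 -2.695, Trim30a -1.021, Ccng1 -1.178 and Siglech 1.188.

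Sham 6 h libraries 1 to 4 lay apart from libraries 5 and 6. A wrong label was argued against: p53 targets differed by a median of -0.085 between libraries 5 and 6 and libraries 1 to 4 (SE 0.139), against 1.811 between irradiated libraries and libraries 1 to 4. A library batch shared with the 2 h libraries is a candidate explanation, since the difference between the sets had r = 0.547 across genes, which are not independent replicates, with that between 1 day and 2 h sham. The sets were split on component 1, on which the 2 h libraries also lie apart, so this r partly restates that choice. It cannot tell a batch from another state shared with the 2 h animals. GC content and length cannot be told apart from other causes as part of the difference between the sets: 292 genes still differed with the trend removed, against 564 and 330 up and down before. No biological explanation was tested, since the labels name no difference among the 6 sham animals.

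Mitosis list reads at 1 week were higher in the irradiated libraries. That 1 or 2 libraries made the difference was argued against, since 6 of 6 lay above every sham library, and so were reads from neural progenitors and neuroblasts, whose markers lay below every sham library in 4 of 6. The library batch seen at 6 h was argued against as the cause of the whole rise: 10 sham libraries on the 2 h side of component 1 had 1.209 times the reads of 8 on the other side (1.664 with 2 standard errors added), against 2.301 times at 1 week (1.861 with 2 taken off). As the cause of a part of it this batch cannot be told apart, since the ratio between sham 6 h libraries 1 to 4 and 5 and 6 was 1.217, between the bounds of 1.2 and 1.5 set for either answer. Reads on the perivascular macrophage list were also 1.638 times as high at 1 week and were not tested as a source, so no cell source is named.

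Interferon-stimulated genes rose at 1 day. Reads from blood monocytes were argued against by Ccr2, at 0.9384 times the sham level, but not by Plac8, at 42.7 RPM against 17.0 (exact permutation p = 0.0325), or by the marker list, at 2.045 times the sham level (adjusted p = 0.0985). The shallow sham library was argued against, since 19 members were called without the libraries of low depth, as with them. GC content and length were argued against, since the median log2 change was 0.939 with the trend removed and 0.961 before. With the monocyte markers divided, a part from such cells that passed the Cx3cr1 sort cannot be told apart from a response of the microglia.

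Other splits of the libraries into groups of the same sizes, 100 each, excluded chance for the counts of genes at each time and for sham libraries over time. The real split alone, 1 of 100, gave as many at 2 h (873, highest other 373), 6 h (2120, highest other 1296), 1 day (435, highest other 233) and 1 week (359, highest other 60). The split with 1296 genes has sham 6 h libraries 1 to 4 on one side, so it follows the structure of that group. With sham libraries 5 and 6 as controls the real split was 1 of 28 (208, highest other 5). For sham libraries over time the real split was 1 of 100 as well (2139, highest other 36). For the differences between times it was 1 of 100 each time (940, 444 and 550, highest other 416, 102 and 55), as over the 4 times (1952, highest other 69). The splits for these differences mixed sham and irradiated libraries within every time, so they stand for no irradiation effect at any time. They cannot decide whether an effect differed between times. For the number of gene lists past the threshold chance was not excluded: 12 of 100 splits gave as many as the 8 at 2 h (highest other 10), 6 as many as the 9 at 6 h (10), 21 as many as the 9 at 1 day (12) and 23 as many as the 3 at 1 week (6). Per list, the real split alone gave as large a median change for p53 targets at each of the 4 times and for homeostatic genes at 2 h, 6 h and 1 day. It did so for disease-associated, inflammatory, complement, lysosomal and ribosomal protein genes at 6 h, for disease-associated, inflammatory, complement, lysosomal, interferon-stimulated and cholesterol efflux genes at 1 day, and for complement and lysosomal genes at 1 week. At 6 h the real split has sham libraries 1 to 4 on one side, so it cannot part irradiation from that structure. With libraries 5 and 6 alone the complement median was -0.072 (0.251 with all 6) and the lysosomal one 0.039 (0.252). Those of disease-associated (0.355 and 0.643), inflammatory (0.568 and 0.599) and ribosomal protein genes (0.22 and 0.496) kept their direction. Chance was not excluded for antigen presentation (17 of 100), unfolded protein (12), interferon-stimulated (9), ribosomal protein (6) and apoptosis genes (6) at 2 h, for histone genes at 6 h (11), for unfolded protein genes at 1 day (28) or for S phase genes at 1 week (5).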

How the results depend on the processing

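Alternatives chosen after seeing the data were the deposited values, voom, sham 6 h libraries set apart, GC content and length removal, and leaving out libraries of low depth. Of 148 values of the main results under alternatives, 101 stayed within 1.5 times. Of 272 named calls, 267 were kept in direction and past the threshold with array weights, 265 with scaling, 257 with a pseudocount of 0.1, 251 with the replicate block, 241 with no filter, 248 with GC content and length removed and 256 without libraries of low depth; voom kept 256 of 267, each time alone 219 of 256, the deposited values 44 of 271, and sham libraries set apart 37 of 95 at 6 h. The replicate block gave 760, 1993, 372 and 251 genes at the 4 times. Apart from the panel, the named calls were picked by size or p in the main fit, so their kept shares do not stand for all calls. Of all 873, 2120, 435 and 359 calls, the replicate block shared 707, 1863, 344 and 210 in direction. With GC content and length removed 814, 1143, 417 and 282 were shared.

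The deposited RPKM, divided by totals of other libraries, gave 52, 64, 39 and 11 genes at 2 h, 6 h, 1 day and 1 week. For the differences between times they gave 3, 0 (limma, 308 at an unadjusted p under 0.05, and 677 by voom on the recovered reads) and 9, over the 4 times 16, for sham over time 670, for overlaps 7, and for genes that rose or fell at all 4 times 4 and 0. By construction these values were 0.436 to 3.11 times those with the own total (5th to 95th percentile). For the rest of this paragraph the cause was not tested. Each time alone gave 542 at 2 h and 254 at 1 day. Sham 6 h libraries set apart gave 208 at 6 h, 75 and 31 for the differences that use 6 h and 848 over the 4 times. With GC content and length removed as well, these were 213, 76, 31 and 872, and 1187 for sham over time. GC content and length removal alone gave 592 and 175 for these differences, 6 lists at 1 week and 2 genes that fell at all 4 times. With it 47.6% of the genes that differed from 2 h to 6 h were higher at 6 h (59.9% before), and 53.1% of those from 6 h to 1 day were higher at 1 day (39.0% before).

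For the following the cause was not tested. Array weights gave 743 at 1 day, 766 at 1 week, and 922 (6 h to 1 day) and 1336 (1 day to 1 week) for differences. Voom gave 690, 931, 677 and 1266 for the same, 6 lists at 1 week and 54 genes that rose at all 4 times. No filter gave 235 at 1 week and 366 for 1 day to 1 week. That difference was 847 without libraries of outlying detection and 874 without libraries of low depth, both of which leave out sham 1 day library 6. An estimated correlation gave 5 lists at 2 h, 2 at 6 h and 1 at 1 week. At 1 week a pseudocount of 0.1 gave 5 lists and scaling 5, and that pseudocount gave 0 genes that fell at all 4 times.

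Calls that turned in direction with sham libraries set apart were Atp5e at 6 h (-0.0155, and -0.0721 with GC content and length removed), Hspa8 at 6 h (0.151 and 0.1428) and Bsg at 6 h (-0.0936 and -0.2138). With both changes C1qb at 6 h (-0.1113) and Jund at 6 h (-0.054) turned too. None of these 8 values passed (adjusted p 0.882 to 1), and the cause was not tested.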

Other observations

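In this part the reads per list and the comparisons with sham 6 h libraries 5 and 6 alone were chosen after seeing the data.

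Among markers of other cell types, summed reads on the astrocyte list rose at 2 h, from 341 ± 73.7 to 754 ± 116 RPM, higher in 6 of 6 irradiated libraries (exact permutation adjusted p = 0.00897). Most of these reads fell on 1 gene, the glutamate transporter Slc1a3 (296 and 724 RPM), which rose by 1.12 ± 0.13. It was the 1 of 3 members past the threshold by limma and 1 of 5 by voom, where the median change was -0.501 (adjusted p = 0.342). At 6 h the astrocyte list was at 332 and 470 RPM (exact permutation adjusted p = 0.00897), with Slc1a3 at 0.38 ± 0.13 and Aldoc at 0.70 ± 0.23, and neither passed with sham libraries 5 and 6 alone (0.46 and 0.65), where the list was at 329.5 RPM. Summed reads on the lymphocyte list fell at 2 h from 46.5 ± 7.44 to 17.9 ± 7.03 RPM, lower in 6 of 6 (exact permutation adjusted p = 0.00897), at 6 h from 51.2 to 18.3 (adjusted p = 0.00897) and at 1 day from 37.3 to 17.0 (adjusted p = 0.0157). Nearly all of these reads fell on Il7r, the interleukin 7 receptor, which changed by -0.75 ± 0.13, -0.80 ± 0.13 and -0.56 ± 0.13 and did not pass at 1 week (-0.26 ± 0.13) or at 6 h with sham libraries 5 and 6 alone (-0.54). Summed reads on the perivascular macrophage list rose at 1 week from 774 ± 112 to 1267 ± 189 RPM, higher in 6 of 6 (exact permutation adjusted p = 0.00897). The scavenger receptor Stab1 carried most of it (676 and 1156 RPM, change 0.75 ± 0.15), the 1 of 4 members past the threshold by limma and 1 of 7 by voom, where the median change was -1.175 and the test pointed down (adjusted p = 0.919), and the mannose receptor Mrc1 was at 62.1 and 86.0 RPM (exact permutation p = 0.0433). At 6 h Mrc1 fell by 0.64 ± 0.11 on the log2 scale, and by 0.52 with sham libraries 5 and 6 alone, which did not pass (adjusted p = 0.0505).

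Progenitor and neuroblast markers were at 53.8 and 165.8 RPM at 6 h (exact permutation adjusted p = 0.00897), with 98.2 in sham libraries 5 and 6 and 31.5 in libraries 1 to 4. The filament gene Nes rose by 1.60 ± 0.23 and by 1.94 with libraries 5 and 6, and Sox4 (2.11 ± 0.69 and 0.08) passed with all 6 only. Neuron markers were at 36.2 and 94.4 RPM at 1 week (exact permutation adjusted p = 0.715), where irradiated library 4 had 393.6 RPM and the other 5 had 19.1 to 50.01, and 0 of them reached the filter of limma. Oligodendrocyte markers were at 0.649, 1.26, 1.00 and 0.753 times the sham level at the 4 times and did not pass (exact permutation adjusted p = 0.332, 0.158, 0.97 and 0.191). Endothelial and mural markers were at 447 and 362 RPM at 1 week (exact permutation adjusted p = 0.0614), and Bsg at 6 h at 0.58 ± 0.17 and -0.09 with libraries 5 and 6. Erythrocyte markers did not pass at any time (exact permutation adjusted p = 0.281, 0.626, 0.761 and 0.761). Monocyte and neutrophil markers were at 15.3 and 12.1, 15.1 and 20.3, 25.0 and 51.1, and 21.5 and 18.9 RPM at the 4 times (exact permutation adjusted p = 0.673, 0.268, 0.0985 and 0.761), with Plac8 past the threshold at 1 day (0.79 ± 0.21). Single genes, Slc1a3, Il7r and Stab1, carried most of the reads of the 3 lists above, so these lists do not name a cell type by themselves.

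Of the remaining lists, DNA damage and repair genes had 2, 2, 1 and 0 of 9 members up at the 4 times and 2 down at 6 h (3, 2, 2 and 0 up and 2 down adjusted over the list alone; adjusted p = 0.0839, 0.793, 0.597 and 0.248). At 1 week 0 passed by limma, 0 at an unadjusted p under 0.05, and 1 of 28 by voom. The mismatch repair gene Msh6 (0.99 ± 0.16) and the checkpoint kinase Chek2 (0.94 ± 0.16) rose at 2 h, and Chek2 by 1.06 ± 0.16 and 1.09 at 6 h with either set. Libraries 5 and 6 alone gave 1 up and 0 down at 6 h (adjusted p = 0.626). At 6 h the median of this list was -0.147 and its mean 0.025, and at 1 day -0.019 and 0.054. S phase genes passed in 0 of 11 at 2 h and 1 day by limma (2 each at an unadjusted p under 0.05, and 0 of 26 by voom; adjusted p = 0.794 and 0.092), and Mcm6 fell at 6 h (-0.44 ± 0.14), where the median was 0.237, the mean 0.102 and the test pointed down (adjusted p = 0.71), and with libraries 5 and 6 alone 0 passed and the median was -0.059. Unfolded protein genes rose in 3 of 15 at 2 h (adjusted p = 0.013, but adjusted p = 0.105 with an estimated correlation), with Herpud1 at 1.16 ± 0.19 and Nupr1 at 0.81 ± 0.24. Sesn2 (3.69), which is also on the p53 list, was among the 3. At 6 h 1 rose and 4 fell, Hspa5 (-0.68), Xbp1 (-0.48) and Dnajb9 (-0.68) among them, with a median of -0.031 and a mean of 0.192 (adjusted p = 0.551). Against libraries 5 and 6 alone 1 rose and 0 fell (median -0.181, adjusted p = 0.781), and at 1 week 1 rose (adjusted p = 0.491). The 1 unfolded protein gene that rose at 6 h and at 1 week was again Sesn2. Ribosomal protein genes rose in 5 of 81 at 2 h (adjusted p = 0.00255, but adjusted p = 0.247 with an estimated correlation), 4 at 1 day (median -0.032, mean 0.022, adjusted p = 0.983) and 1 at 1 week (adjusted p = 0.8), with Rps27l at 1.98, 1.65 and 1.13.

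Histone genes fell in 3 of 38 at 6 h (adjusted p = 0.00947, but adjusted p = 0.215 with an estimated correlation), and 6 with GC content and length removed (median -0.687). With sham libraries 5 and 6 alone no single gene passed, while the median was -0.706 against -0.312. The list then had adjusted p = 1.03e-05 at the preset correlation, and the estimated correlation was not run. Hist1h1b rose at 1 week (1.75 ± 0.43). Hist3h2a was the 1 that fell at 2 h, and at 1 day 0 passed by limma and by voom (4 and 5 at an unadjusted p under 0.05). Apoptosis genes rose in 4 of 19 and fell in 2 at 6 h (adjusted p = 0.247; 2 up and adjusted p = 0.0106 with libraries 5 and 6), with Bcl2l1 at 1.31 ± 0.17 and 1.12, rose in 2 at 1 day (4 up and 1 down adjusted over the list alone, adjusted p = 0.178) and in 3 at 1 week (adjusted p = 0.239), with Casp8 at 0.77 ± 0.19. Bax, also on the p53 list, was among the apoptosis genes that rose each time. Complement genes rose in 1 of 18 at 1 week (6 up and 2 down adjusted over the list alone, adjusted p = 0.0637), Gas6 (0.95 ± 0.21). Lysosomal genes had 1 up and 1 down at 2 h (3 and 4 adjusted over the list alone, adjusted p = 0.144), Ctss (0.50) and Lipa (-0.61). Cholesterol efflux genes had Abcg1 down at 2 h (-0.97, adjusted p = 0.407) and 5 up and 2 down at 6 h (adjusted p = 0.159), 0 of them with libraries 5 and 6 (median 0.183 with these against 0.185). Cholesterol synthesis genes passed in 3 of 13 at 6 h, Mvd, Srebf2 and Tm7sf2 (adjusted p = 0.584; 0 with libraries 5 and 6), and 0 at the other times by limma (4, 2 and 3 at an unadjusted p under 0.05; voom 0, 0 and 3). Oxidative phosphorylation genes had 1, 6, 1 and 0 of 28 up and 1 down at 6 h and 1 day (adjusted p = 0.27, 0.163, 0.893 and 0.313), with a median of -0.08 and a mean of 0.046 at 1 day, and 0 at 6 h with libraries 5 and 6 (median -0.037). Glycolysis and hypoxia genes had 1 up and 2 down of 13 at 2 h (median -0.011, mean 0.013), 5 up and 1 down at 6 h (0 with libraries 5 and 6, median 0.188), 0 at 1 day by limma and by voom (0 at an unadjusted p under 0.05) and Pdk1 down at 1 week (adjusted p = 0.867, 0.113, 0.639 and 0.239). Immediate early genes, which also mark cell handling, had 0, 3, 1 and 0 of 25 past the threshold, and 0 at 6 h with libraries 5 and 6 (adjusted p = 0.152, 0.907, 0.239 and 0.239). At 2 h and 1 week, where 0 passed by limma, 4 and 6 did at an unadjusted p under 0.05, and voom called 1 and 4.

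The summed reads of a list, which follow its most abundant members, passed in places where the list test did not. Exact permutation adjusted p values follow each list. At 6 h these were cholesterol efflux (1.107 times the sham level, 0.0407), glycolysis (1.165 times, 0.0222) and apoptosis genes (1.198 times, 0.0407). At 1 day they were antigen presentation (1.168 times, 0.0439) and apoptosis genes (1.281 times, higher in 6 of 6, 0.00897). At 1 week they were DNA damage and repair (595.4 and 760.5 RPM, higher in 5 of 6, 0.0157), complement (1.131 times, 6 of 6, 0.00897), apoptosis (1.174 times, 6 of 6, 0.00897), oxidative phosphorylation (1.167 times, 0.0287) and ribosomal protein genes (1.279 times, 0.0439). The sums of homeostatic (0.6644 times, 0.00897), cholesterol efflux (0.8373 times, lower in 6 of 6, 0.00897) and lysosomal genes (0.9391 times, 0.0439) were lower at 1 week. The homeostatic sum holds Cst3, which alone took 8.58% of all reads in sham and 3.43% in irradiated libraries. By limma 2 homeostatic genes rose and 2 fell at 1 week. The sums did not pass where the list test did for homeostatic (0.134), interferon-stimulated (0.134), ribosomal protein (0.216), unfolded protein (0.574) and apoptosis genes (0.0571) at 2 h. The same held for homeostatic (0.84), lysosomal (0.0871) and histone genes (0.746) at 6 h, homeostatic genes at 1 day (0.134) and disease-associated genes at 1 week (0.19).

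Sham libraries differed over time for 2139 genes, and for 1783 with sham 6 h libraries 1 to 4 set apart, a comparison in which age, day and library batch are not separated. The 10 with the smallest p were Rmrp (log2 means 5.06, 6.97, 10.9 and 9.98 at the 4 times), Fam91a1, Snx5, Fscn1, Pdia3, Actb (9.74, 10.1, 10.8 and 10.5), Sparc, Cotl1, Rpph1 and Pfn1. Cst3 took 8.58% ± 2.46 of the reads in sham and 3.43% ± 1.30 in irradiated libraries at 1 week. Sham 1 day library 6 had a median rank correlation of 0.652 with its group. At 6 h, 1 day and 1 week libraries of the same number had r from -0.107 to 0.079 across genes, which are not independent replicates. At 2 h r was 0.016 to 0.137 for the same number, against a mean of -0.015 for other numbers, and the own number was the best match in 4 of 6. Reads on inflammatory cytokines and NF-kB targets at 2 h were 5104 to 5888 RPM in sham libraries 1 to 3 and 2269 to 2725 in 4 to 6, and 7555 to 9043 and 5966 to 6261 in the irradiated ones. The labels give no batch for these sets, and with the replicate block 760, 1993, 372 and 251 genes changed at the 4 times.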
